A study of Mus musculus with 37 samples.

How the data were processed

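RNA was sequenced in bulk from subcutaneous mouse tumours collected 3 weeks after clones of pancreatic tumour cells were implanted into C57BL/6 mice, per the labels' protocols. The labels name Qiagen columns for the extraction, an input of 500 ng per library, an NEB kit for the libraries and an Illumina NextSeq instrument. The deposited table holds read counts per gene for 37 libraries, 1 per tumour. STAR, featureCounts and the genome build mm10 are named in the submitters' processing notes. The versions, the annotation, the strand setting and the treatment of reads that fit several genes are not given in the sources used here, so genes with near-identical copies and overlapping or antisense genes are uncertain. The table holds 39017 genes as whole-number counts that were not normalised, judged from the values. Of its identifiers, 37607 were found in GENCODE M21 (GRCm38), which gave the coordinates, and 1410 were not. The symbols printed are those of the deposited table.

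Total counts of the 34 libraries with a T cell phenotype ranged from 7.39 to 102.33 M, with a median of 31.8 M. The phenotype labels high, low and intermediate cover 15, 15 and 4 tumours from 7, 7 and 2 clones, and 3 tumours have no phenotype label. How the phenotype was measured is not given in the sources used here. Lists of T cell genes therefore check the label and are no independent evidence about it. Tumours of 1 clone share the implanted cells, so the clone was the replicate and the counts of its tumours were summed. The meaning of the number before the letter c in a clone name is also not given in the sources used here.

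Genes were tested on the clone sums with edgeR 4.0.16 (R 4.3.3), using TMM scaling, the default expression filter by group and the two-sided quasi-likelihood test. The model had 1 coefficient per phenotype over all 16 clones. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The filter left 20348 genes. Standard errors (SE) of log2 differences were taken as the absolute difference divided by the square root of the F statistic and are approximate. Levels of phenotypes are in CPM with TMM scaling, given as the mean and SD over clones. The levels of liver and heart transcripts per library, and of Cd8a in libraries without a phenotype, are CPM of the total counts without that scaling. Clones that share a number were compared on counts per tumour, with 1 coefficient per clone over 34 tumours and 20421 genes.

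The 31 gene lists (437 memberships), the 24 preset genes, the tests and most alternatives were chosen before the data were examined. Lists were tested with camera at a preset correlation of 0.01 between genes (limma 3.58.1), with camera at an estimated correlation, and with fry, which asks whether the genes of a list move on balance in 1 direction. An exact two-sided permutation test compared the mean log2 CPM of a list per clone (prior count 2). The smallest p that it can give is 0.000583 for 7 against 7 clones. All list tests were adjusted over the 31 lists.

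The lists covered T cells, cytotoxic effectors, inhibitory receptors and ligands, regulatory T cells, NK cells, B cells, plasma cells, cDC1 dendritic cells, mature dendritic cells, macrophages and monocytes, granulocytes, and mast cells and eosinophils. They also covered granulocyte-attracting and growth factors, T cell-attracting chemokines, the interferon response, MHC class I and class II presentation, fibroblasts and collagen matrix, smooth muscle and pericytes, endothelial cells, ductal epithelial genes and mesenchymal transition. The rest were the cell cycle, MYC and ribosome biogenesis, hypoxia and glycolysis, MAPK pathway feedback, subcutaneous fat, skeletal muscle, skin epidermis and hair, red blood cells and mitochondrially encoded genes. The lists of T cells and cDC1 dendritic cells share no genes with any other list.

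Genes named in the text follow a rule set in advance. The preset genes are always named. From the comparison of high with low clones, the 8 called genes with the largest difference in each direction were to be named, and none was called. From each list, up to 3 called members are named, or else the member with the smallest p. Called was read there as past the threshold when adjusted over the list alone, a reading chosen after the data were seen. From the other comparisons, up to 5 called genes per direction with at least 1 CPM are named, leaving out predicted genes. Relations between list scores over clones used Pearson's r and Spearman's rho with exact two-sided permutation tests over all pairings, within each phenotype, with 8 relations per family.

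Libraries were sorted by the sum of Myh6, Myh7, Cps1 and Serpina3k, with over 10 CPM counted as having liver and heart transcripts. This rule was chosen after the data were seen. The list scores and ductal genes without bulk_7160c2 were also computed after its levels were seen. The same tests were repeated on libraries of each class alone, and a class term was added to models on tumours. Similarity between libraries was computed over genes with at least 50 counts as a chi-squared value per gene, which is near 1 for libraries that differ by counting noise alone.

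Alternatives were edgeR with RLE factors, DESeq2 1.42.0, no filter, a stricter filter, tumours as replicates, limma voom with a correlation within clones, 1 tumour per clone, the number in the clone name as a block, only the 14 high and low clones, and each clone or tumour left out in turn. The steps were tested on simulated counts with 200 changed genes. Between high and low clones edgeR called 47% of genes changed by a log2 of 1 and 80.6% of those changed by 2, among 19900 genes tested, and 1.56% of its calls were false. DESeq2 called 58% and 91% among 20348 genes, with 19% of its calls false. limma voom called 63.6% and 88.9% among 18356 genes, with 5.03% false, on tumours drawn without a clone effect. The test of the bulk_6499 clones called 43% of genes changed by 2 and 69.4% of those changed by 4 among 19679 genes, with 3.48% false. With 1 list raised among 31 over 19892 genes, camera called that list alone under both correlations. The simulated genes were drawn independently of each other. This run therefore cannot tell how either correlation performs on genes that move together, such as the T cell list (estimated correlation 0.689 between high and low clones). Python 3.11.15 with SciPy 1.17.1 was used for relations and matplotlib 3.10.9 for plots. The 3 libraries without a phenotype were left out of all comparisons, and 1 result on them is not reported here. The SD of a single gene holds counting error as well as differences between clones.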

Results

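Bulk RNA was measured in 37 mouse tumours grown from implanted clones of pancreatic tumour cells. The labels call 15 tumours of 7 clones T cell high, 15 tumours of 7 clones T cell low and 4 tumours of 2 clones T cell intermediate, and 3 tumours have no phenotype. Clones are named by the start of the sample titles, such as bulk_2669c4, and the plots leave out the prefix. Total counts averaged 36.9 ± 19.6 M (SD, n = 15 libraries) for high, 30.2 ± 8.48 M (n = 15) for low and 53.8 ± 33.1 M (n = 4) for intermediate tumours. The shallowest library, of low clone bulk_6499c3, held 7.39 M counts and the deepest of the 34, of intermediate clone bulk_7160c5, held 102.33 M.

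Liver and heart genes were abundant in 17 of the 34 libraries. Alb, the liver gene for serum albumin, reached 7558 CPM and Myh6, the heart muscle myosin, 1496 CPM. The summed level of Myh6, Myh7, Cps1 and Serpina3k was 257.7 to 5922 CPM in these libraries and at most 0.539 CPM in the other 17. Alb is not in that sum. Of the other 17, bulk_6419c1_no2 still held Alb at 123.6 CPM. It was at 16.7, 16.4 and 10.8 CPM in bulk_6499c3_no2, bulk_6422c5_no2 and bulk_2838c3_no2, and at most 4.82 CPM in the rest. The 17 libraries with the transcripts came from 7 high, 8 low and 2 intermediate tumours, and the 17 without from 8, 7 and 2. All 16 tumours numbered 1 had them, with 1 tumour numbered 2, from low clone bulk_2669c4. None of the 14 other tumours numbered 2, the 2 numbered 3 or the 1 numbered 4 had them. The first principal component of the libraries held 45.0% of the variance and separated the 2 classes. Relative to the highest library, the level averaged 64.1 ± 39.6% (SD, n = 7) in high and 52.0 ± 23.8% (n = 8) in low libraries with the transcripts, a difference within the spread (two-sided exact permutation p = 0.471). It was only 4.90% and 4.35% in the 2 intermediate libraries with the transcripts. Each comparison was therefore repeated on the 17 libraries at or below 0.539 CPM of the 4 summed genes, called here those without the transcripts. The clone sums hold libraries of both classes. The 4 libraries with the highest levels came from different clones and were nearly alike, with a chi-squared value per gene of 3.48 to 9.42 between them. Next came bulk_6556c4_no1, bulk_6620c1_no1 and bulk_6694c2_no1, at 69.97% to 74.51% of the highest level. They gave 10.06 to 44.1 with each other and with the 4, below the 59.3 of the closest pair from 1 clone. Of all these libraries, only bulk_6419c5_no1 and bulk_6694c2_no1 are of low clones, and the others are of high clones. The 4 libraries show little of their own clones, and what the shared content did to differences between clone sums was not tested.

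**Figure D1:**
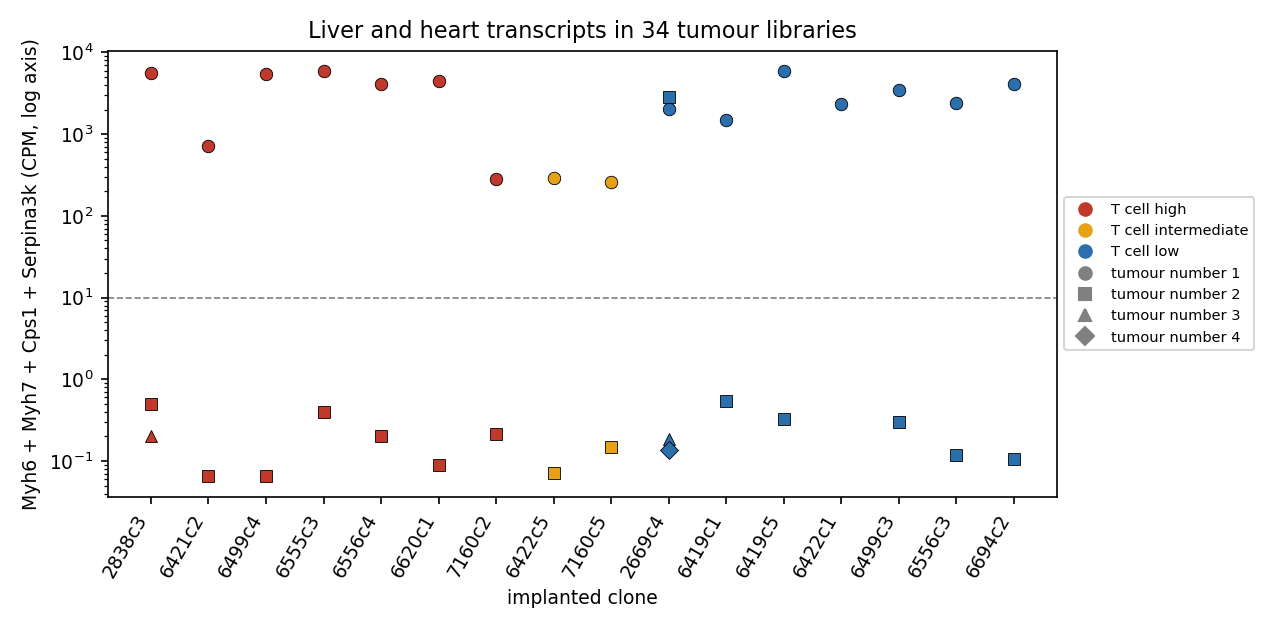
Summed level of Myh6, Myh7, Cps1 and Serpina3k in CPM (log axis) in each of 34 libraries, by clone, coloured by phenotype, with the tumour number as the symbol and the limit of 10 CPM as a dashed line. The 17 libraries with liver and heart transcripts lie between 257.7 and 5922 CPM and the 17 without lie at or below 0.539 CPM.

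The comparison of high with low tumours asked which genes accompany a rich T cell infiltrate. Cd8a, the co-receptor of cytotoxic T cells (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173), averaged 1.85 ± 1.92 CPM (SD, n = 7 clones) in high and 0.404 ± 0.276 CPM (n = 7) in low clones, a log2 difference of 2.16 (SE 0.73). Pdcd1, which encodes the inhibitory receptor PD-1 (chromosome 1, 94038305 to 94052553), averaged 1.99 ± 1.49 against 0.669 ± 0.278 CPM, a log2 difference of 1.56 (SE 0.44). Cxcl1, a chemokine that attracts neutrophils (chromosome 5, 90891241 to 90893115), averaged 14.8 ± 7.59 CPM in high and 31.1 ± 17.4 CPM in low clones, a log2 difference of -1.08 (SE 0.38). Krt19, a keratin of ductal cells, was at 1213 ± 341.8 and 1231 ± 336.8 CPM. None of these differences passed the edgeR test, with an adjusted p of 0.659 for Cd8a, Pdcd1 and Cxcl1 over all genes, and 0.0545 adjusted over the list alone of 24 preset genes. In the 4 nearly alike libraries Cxcl1 was at 25.5 to 27.2 CPM of total counts, against 1.23 to 11.1 CPM in the other tumours of their clones. Cd8a was at 0.0495 to 0.194 CPM in the 4, against 0.391 to 6.10 CPM in those other tumours. The levels given for clones therefore include levels that these libraries share.

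Over 20348 genes, edgeR called 0 genes between high and low clones, and the smallest adjusted p was 0.659. At an unadjusted p under 0.05 there were 1516 genes, 7.45% of those tested, with 878 higher and 638 lower in high clones. Leaving out the high clone bulk_7160c2 reduced that count to 994. DESeq2 called 25 genes (23 higher and 2 lower), edgeR on tumours ignoring the clone called 38 (26 higher and 12 lower), and limma voom with a correlation within clones called 0. With only the libraries without liver and heart transcripts, edgeR called 0 of 17905 genes, with 1168 at an unadjusted p under 0.05, and in those with the transcripts 0 of 18830, with 2116. Of the 24 preset genes, 0 were called when adjusted over the list alone, and 14 had a positive difference.

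Markers of T cells and of the dendritic cells that prime them lay higher in high clones without passing the test. The log2 difference was 1.33 (SE 0.47) for the T cell receptor component Cd3e, 1.35 (SE 0.49) for Foxp3 of regulatory T cells, 1.44 (SE 0.54) for the T cell chemokine Ccl5 and 1.19 (SE 0.40) for Xcr1, the chemokine receptor of cross-presenting dendritic cells. Batf3, the transcription factor of those cells, differed by 0.79 (SE 0.34), their integrin Itgae by 0.90 (SE 0.35), Cd4 by 0.63, Ifng by 1.12 (SE 0.93) and the interferon-induced Cxcl9 by 0.79 (SE 0.73). Without the high clone bulk_7160c2 the difference fell to 0.57 for Foxp3, 0.13 for Cd4 and 0.78 for Ccl5. In the libraries without liver and heart transcripts the difference was 1.93 for Cd8a, 1.45 for Pdcd1, 0.72 for Cd3e, 0.59 for Foxp3, 0.99 for Ccl5, 0.85 for Xcr1 and -1.67 for Cxcl1. It was much smaller there for Ifng (0.15), Cd4 (0.19), Csf3 (0.21), Csf2 (-0.09) and S100a8 (-0.02). The cytotoxic granule genes Gzmb and Prf1 differed by -0.34 (SE 0.49) and -0.28 (SE 0.60), and both signs turned positive without the low clone bulk_2669c4, at 0.16 and 0.38. Genes of neutrophil recruitment gave -0.52 for Cxcl5, -0.35 for Csf2, 0.70 for Csf3, -0.29 for S100a8 and -0.36 for Cxcr2. Cxcl10 gave -0.26, the macrophage arginase gene Arg1 0.06, Cd274, which encodes PD-L1, 0.01, Myc -0.27 and Krt19 -0.02. The sign for Csf3 turned negative without the high clone bulk_7160c2, at -0.12, and those for Cd274 and Krt19 changed under several alternatives. The sign turned positive for Csf2 without bulk_6556c3, at 0.17, for S100a8 without bulk_6419c1, at 0.08, and for Myc without bulk_2669c4, at 0.11, and negative for Arg1 without bulk_6556c3, at -0.02.

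**Figure D2:**
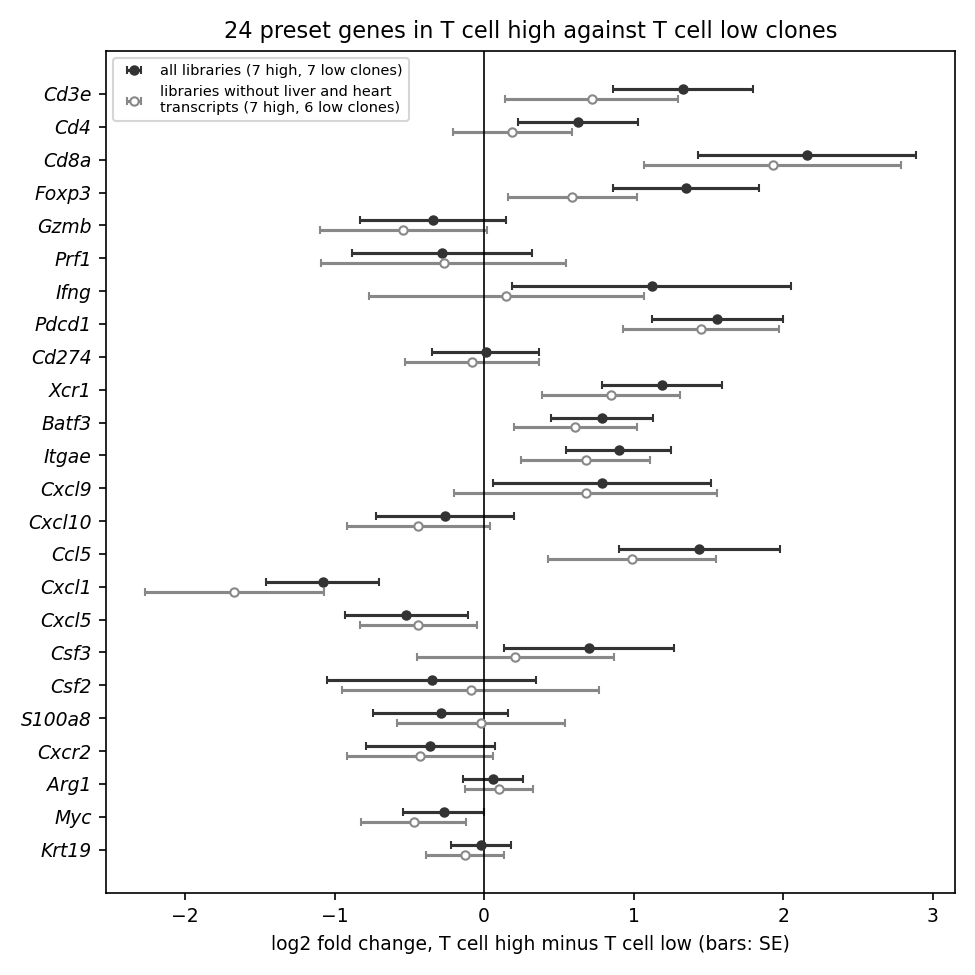
Log2 difference between high and low clones of the 24 preset genes with its SE, in all libraries (filled, 7 high and 7 low clones) and in the libraries without liver and heart transcripts (open, 7 high and 6 low clones). Cd8a lies at 2.16 and 1.93, Cxcl1 at -1.08 and -1.67, and no gene passed the test.

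By calls adjusted over the list alone, T cell genes were the clearest group in all libraries. Of the 20 in the list, 19 lay higher in high clones and 11 were called when adjusted over the list alone. Trbc2, a constant gene of the T cell receptor, averaged 2.30 ± 1.12 CPM (SD, n = 7) in high and 0.729 ± 0.255 CPM (n = 7) in low clones, a log2 difference of 1.66 (SE 0.35). Cd3g, of the receptor complex, differed by 1.54 (SE 0.47) and the signalling kinase Zap70 by 1.05 (SE 0.33). Only Trbc2 was called in this list in the libraries without liver and heart transcripts, at 2.24 (SE 0.51). Reads of Trbc2 can be shared with its copy Trbc1. In addition, 3 epithelial genes were called among 19 ductal genes when adjusted over the list alone: the tight junction gene Cldn7 (2.10, SE 0.60), the splicing regulator Esrp1 (2.80, SE 0.83) and the adhesion gene Epcam (2.12, SE 0.67). Cldn7 and Esrp1 were also called in the libraries without the transcripts, at 2.76 and 3.76, and Epcam was not (1.96, SE 0.85). The high clone bulk_7160c2 stands apart on this list, and without it none of the 3 was called, at 1.72 (SE 0.58), 1.60 (SE 0.64) and 1.61 (SE 0.62), each with an edgeR adjusted p = 0.154 over the list alone.

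Across lists, camera with the preset correlation called 12 of 31 between high and low clones, 10 higher and 2 lower in high clones. T cells (adjusted p = 3.55e-12), MHC class II presentation (1.39e-04), cDC1 dendritic cells (4.21e-04), regulatory T cells (0.00165), MHC class I presentation (0.00179), and fibroblasts and collagen matrix (0.00294) lay higher. Ductal epithelial genes (0.0189), smooth muscle and pericytes (0.0240), mature dendritic cells (0.0369) and cytotoxic effectors (0.0438) did so too. The cell cycle list (1.04e-05) and the hypoxia and glycolysis list (0.00179) lay lower. Each of the 12 lists had an adjusted p = 0.718 with an estimated correlation, and fry called 0 lists. By the exact permutation test of scores, 4 lists had an unadjusted p under 0.05, regulatory T cells (0.00874), T cells (0.0309), ductal epithelial genes (0.0326) and cDC1 dendritic cells (0.0466), and 0 passed after adjustment, with a smallest adjusted p of 0.271. Without bulk_7160c2 the exact permutation p was 0.0181 for regulatory T cells and 0.067 for ductal epithelial genes. In the libraries without liver and heart transcripts camera with the preset correlation called 5 lists higher (T cells, cDC1 dendritic cells, both MHC lists and mitochondrially encoded genes) and 5 lower (cell cycle, hypoxia and glycolysis, granulocyte-attracting and growth factors, MYC and ribosome biogenesis, and mesenchymal transition). Each of those 10 had an adjusted p = 0.806 with an estimated correlation. The mitochondrially encoded list lay lower in high clones in the libraries with the transcripts, with a median log2 difference of -0.65, and higher in those without, at 0.74.

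The genes named next had the smallest p of their lists, so their sizes are not typical of the lists. The regulatory T cell list, for example, had a median log2 difference of 0.54. H2-Eb1, of MHC class II, had a log2 difference of 0.74 (SE 0.39) and H2-Q7, of class I, whose reads can be shared with its close copies, 1.25 (SE 0.47). The fibroblast gene Thy1 differed by 0.50 (SE 0.22), the smooth muscle actin Acta2 by 0.57 (SE 0.27), the regulatory T cell receptor Ccr8 by 1.80 (SE 0.60) and Ccl22 of mature dendritic cells by 1.34 (SE 0.48). The survivin gene Birc5, expressed in dividing cells, differed by -0.50 (SE 0.20), and 21 of 22 cell cycle genes lay lower in high clones, with a median of -0.26. The glycolytic enzyme gene Pgk1 differed by -0.48 (SE 0.24). None of these genes was called when adjusted over its list alone.

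The other lists were not called between high and low clones in all libraries. Their members with the smallest p were Il2rb for NK cells (1.30), Spib for B cells (1.02), Prdm1 for plasma cells (0.45), Spp1 for macrophages and monocytes (-0.77), Camp for granulocytes (1.25) and Kit for mast cells and eosinophils (0.79), as log2 differences. Cxcl1 led the granulocyte-attracting factors, Ccl5 the T cell-attracting chemokines and Ido1 the interferon response (0.87). Vwf (0.45) led the endothelial list, S100a4 (-0.75) mesenchymal transition, Npm1 (-0.43) MYC and ribosome biogenesis, Etv5 (0.32) MAPK pathway feedback and Fabp4 (-0.97) subcutaneous fat. Tnni2 (0.20) led skeletal muscle, Krt25 (2.72, at 0.0989 against 0.0131 CPM) skin epidermis and hair, Epb4.2 (0.44) red blood cells and mt-Nd3 (-1.31) the mitochondrially encoded genes. In the list of inhibitory receptors and ligands, which camera did not call, Pdcd1 alone of 12 genes was called when adjusted over the list alone. For mast cells and eosinophils, and for mitochondrially encoded genes, the median and the test had opposite signs.

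**Figure D3:**
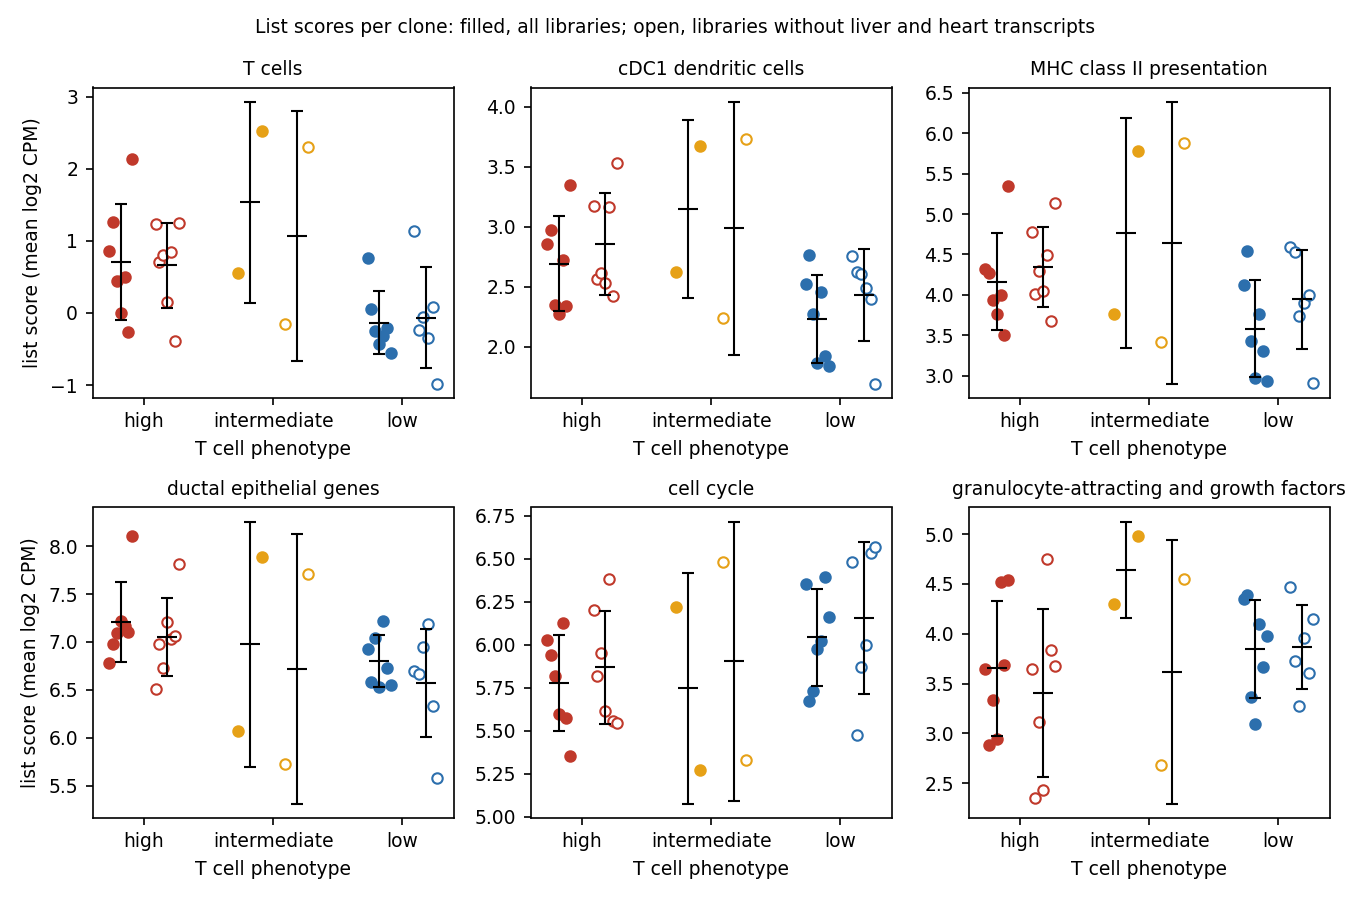
Mean log2 CPM of 6 gene lists per clone, by phenotype, with the group mean and SD, in all libraries (filled) and in the libraries without liver and heart transcripts (open). In all libraries the T cell score of intermediate clone bulk_7160c5 (2.53) is the highest, and the high clones bulk_6620c1 (-0.26) and bulk_6555c3 (-0.01) lie below the low clone bulk_2669c4 (0.76).

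The comparison of intermediate with low tumours rests on 2 intermediate clones. Foxp3 averaged 6.90 ± 7.44 CPM (SD, n = 2) in intermediate and 0.943 ± 0.186 CPM (n = 7) in low clones, a log2 difference of 2.87 (SE 0.64). Ccl5 differed by 2.80 (SE 0.71), Cd8a by 2.52 (SE 0.93), Pdcd1 by 2.41 (SE 0.57), Cd3e by 2.25 (SE 0.62), the granulocyte growth factor Csf3 by 2.10 (SE 0.76), Cd4 by 1.94 (SE 0.53), Xcr1 by 1.46 (SE 0.54) and Itgae by 1.36 (SE 0.49). These 9 of the 24 preset genes were called when adjusted over the list alone, and Foxp3 alone in the libraries without liver and heart transcripts, at 2.23 (SE 0.57). Over all genes edgeR called 0, with a smallest adjusted p of 0.132 and 3261 genes at an unadjusted p under 0.05. DESeq2 called 939 (328 higher and 611 lower), edgeR on tumours ignoring the clone 421, and limma voom 130, or 8 with the library class as a term. The 2 intermediate clones lay far apart, with a T cell score in all libraries of 2.53 in bulk_7160c5 and 0.55 in bulk_6422c5. Single clones changed the count, which was 567 without high clone bulk_7160c2, which is in neither group, and 9 without low clone bulk_6499c3. Leaving out an intermediate clone leaves 1 in that group, so those counts are not given.

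All 20 fibroblast and matrix genes and 18 of 20 T cell genes lay higher in intermediate than in low clones and were called when adjusted over the list alone, against 9 of 11 skeletal muscle genes lower. camera with the preset correlation called 19 lists higher and 4 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.195. fry called 8 lists, and the permutation test 0 after adjustment, with 0.0278 the smallest p that 2 against 7 clones can give. In the libraries without liver and heart transcripts camera called 10 lists higher and 4 lower with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.444), and fry called 0. The skeletal muscle list was among the 4 lower lists in all libraries and not in the libraries without the transcripts, and the intermediate clones bulk_6422c5 (4.90%) and bulk_7160c5 (4.35%), with high clone bulk_7160c2 (4.77%), held the lowest relative levels of these transcripts.

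The comparison of high with intermediate tumours gave lower T cell markers in high clones, within the spread. The log2 difference in all libraries was -1.51 (SE 0.66) for Foxp3, -1.30 (SE 0.55) for Cd4, -0.93 (SE 0.65) for Cd3e, -0.85 (SE 0.60) for Pdcd1 and -0.36 (SE 1.0) for Cd8a. In the libraries without liver and heart transcripts it was -1.64 (SE 0.56) for Foxp3, -1.23 (SE 0.54) for Cd4 and -1.13 (SE 0.77) for Cd3e. There the difference was gone for Pdcd1 (0.01, SE 0.72) and of the other sign for Cd8a (0.22, SE 1.18). edgeR called 0 genes, with a smallest adjusted p of 0.303 and 2099 at an unadjusted p under 0.05, and 0 of the 24 preset genes when adjusted over the list alone. DESeq2 called 534 (459 higher and 75 lower) and edgeR on tumours ignoring the clone 4. The count was 1 without high clone bulk_7160c2. Counts without an intermediate clone, which leave 1 in that group, are not given. In the libraries without liver and heart transcripts edgeR called 0 genes higher and 1 lower, 2610018G03Rik, at -3.57 (SE 0.46, adjusted p = 0.0210), which is named after its values were seen. camera with the preset correlation called 4 lists higher and 16 lower, 0 with an estimated correlation (smallest adjusted p = 0.215), and 4 and 6 in the libraries without the transcripts, where an estimated correlation again left 0 (smallest adjusted p = 0.119).

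Clones that share the number before the letter c allow a high and a low clone to be compared within a number. In bulk_6499c4 (high) against bulk_6499c3 (low), with 2 tumours each, the protocadherin gene Pcdhb16 fell by 3.73 on the log2 scale (SE 0.57, edgeR adjusted p = 0.0198) and Pcdhb19 fell by 2.84 (SE 0.44, adjusted p = 0.0198). Pcdhb16 was at 15.04 and 22.9 CPM in the tumours of bulk_6499c3 and at 1.70 and 1.16 CPM in those of bulk_6499c4. Pik3ca, the catalytic subunit of PI3 kinase, fell by 1.26 (SE 0.20, adjusted p = 0.0238) and the transcription factor gene Taf2 fell by 0.88 (SE 0.15, adjusted p = 0.0333). Tmem52b was the 1 gene called higher (adjusted p = 0.0341). It lies below 1 CPM on average and is named after its values were seen. The counts of 1 higher and 4 lower among 20421 genes stood beside 1240 at an unadjusted p under 0.05, 51 calls by DESeq2 and 15 with the library class as a term. They became 0 without a filter on low counts and 0 with only the 4 tumours of these clones. Leaving out a tumour leaves 1 in its clone, so no conclusion is drawn from counts without a tumour. The library bulk_6499c4_no1 is 1 of 4 from different clones that are nearly alike. Its chi-squared value per gene was 3.48 against bulk_6555c3_no1, and 316 against the other tumour of its own clone, whose library lacks the liver and heart transcripts. Protocadherin genes have near-identical copies, so their reads can be shared.

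In bulk_6556c4 (high) against bulk_6556c3 (low), Cd274 differed by 1.80 (SE 0.68), where in the bulk_6499 clones it differed by -1.74 (SE 0.68), and neither passed the test. It was at 16.9 and 61.8 CPM in the tumours of bulk_6556c4 and at 6.87 and 15.7 CPM in those of bulk_6556c3. The difference between the bulk_6556 clones thus leaned on bulk_6556c4_no2. The library bulk_6556c4_no1 had a chi-squared value per gene of 10.06 against bulk_6694c2_no1, of another clone. Against the other tumour of its own clone the value was 357. Cd8a differed by 1.68 (SE 1.29) in the bulk_6556 clones and by -0.10 (SE 1.48) in the bulk_6499 clones. edgeR called 0 genes between the bulk_6556 clones, with 818 at an unadjusted p under 0.05, and DESeq2 called 2. The test of the difference between the 2 numbers called 0 genes with edgeR, with a smallest adjusted p of 0.529 and 796 genes at an unadjusted p under 0.05. It was not run with DESeq2.

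The cDC1 dendritic cell score rose with the T cell score over the 7 high clones (Pearson r = 0.949, exact permutation p = 0.000595, adjusted p = 0.00476 over 8 relations). Spearman's rho was 0.964 (exact permutation p = 0.00278, adjusted p = 0.0222), and r was 0.905 without the 2 clones farthest from the median. In the libraries without liver and heart transcripts r was 0.802 (exact permutation p = 0.0258, adjusted p = 0.206) and rho 1.0 (adjusted p = 0.00317), so by Pearson's r the relation did not pass within that class. In those with the transcripts r was 0.971 (adjusted p = 0.0312 by the exact permutation test) in high clones and 0.559 without the 2 farthest clones, and 0.871 (adjusted p = 0.00159) in low clones, and the fibroblast score also rose with the T cell score in high clones (r = 0.907, adjusted p = 0.00714). That relation had the opposite sign in the libraries without the transcripts, with r = -0.581 in high clones (adjusted exact permutation p = 0.328) and r = -0.827 in 6 low clones (adjusted exact permutation p = 0.272, rho = -0.943). Over the 7 low clones r was 0.638 (exact permutation p = 0.0954, adjusted p = 0.382) and rho 0.821 (adjusted p = 0.137), and whether the relation differs between phenotypes was not tested. In all libraries no relation of the T cell score passed with the granulocyte score (r = -0.02), the fibroblast score (r = 0.33) or Cxcl1 (r = -0.02) in high clones, nor in low clones (r = 0.44, -0.40 and 0.43). Their adjusted exact permutation p lay between 0.596 and 0.974. Among the high libraries with the transcripts, those of bulk_7160c2 and bulk_6421c2 had the lowest relative levels of them, 4.77% and 12.05%. Cd3e was at 4.69 and 4.46 CPM of total counts there, against 0.573 to 1.43 CPM in the others, at 69.97% to 100%. These are the 2 clones whose removal lowered r to 0.559. The clone sums hold the same libraries, and whether the differing levels made these relations was not tested.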

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

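The tests of liver and heart transcripts and of the cell cycle genes weighed here were chosen after the result was seen. The wording of 1 of them (whether the transcripts follow the phenotype) and the bar for both tests of the cell cycle genes were changed after their values were known. By a bar on the exact permutation p, liver and heart RNA would have stayed open. By the first bar, on the median alone, a lower share of tumour cells would have been argued against.

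Among 110 groups of 7 clones, 1 for each of 31 lists and 24 preset genes in high and in low clones, 11 had a clone far from the others by the ratio of its gap to the nearest clone over the whole range. Chance alone marks about 1 in 20 such groups, here 5.5. The low clone bulk_2669c4 lay above the other low clones for the cytotoxic effectors (ratio 0.645), NK cells (0.673), Ifng (0.679), Ccl5 (0.615) and Myc (0.618). Its Myc level of 8.53 in log2 CPM stood against 6.37 to 7.20 in the others. The high clone bulk_7160c2 lay above the other high clones for regulatory T cells (0.662), mature dendritic cells (0.668), ductal epithelial genes (0.671), Cd4 (0.583) and Foxp3 (0.795). Its Foxp3 level was 3.06 against 0.27 to 0.84 in the others. The high clone bulk_6555c3 lay below the others for mast cells and eosinophils (0.582). No explanation was tested for these clones.

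Among libraries that enter no comparison, the unassigned bulk_6883c4_no1 held Cd8a at 31.1 CPM, and bulk_6883c1_no1 held Cd8a at 8.47 CPM. The 34 libraries with a phenotype reached at most 6.5 CPM for Cd8a. Some lists of other immune cells lay above the 34 in both libraries too, and not all are printed, so Cd8a does not mark them as rich in T cells alone. No test was run on the origin of these signals.

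The presence of liver and heart transcripts in 17 of 34 libraries does not follow the phenotype, since 15 of 16 clones had 1 library with them and another without. Their levels differed between high and low libraries by less than the spread (exact permutation p = 0.471), and the low levels of the 2 intermediate libraries with them (4.90% and 4.35%, beside 4.77% in high clone bulk_7160c2) were not tested. The ratio of liver to heart transcripts was 2.42 on average, between 2.19 and 2.83, with a CV of 6.59%, which is consistent with 1 common mixed source in different shares. A source of liver and heart RNA alone is argued against by the 4 libraries with the highest levels (bulk_2838c3_no1, bulk_6419c5_no1, bulk_6499c4_no1 and bulk_6555c3_no1). Their spread between clones of 500 clone-variable genes was 16.5% of that in libraries of the same clones without the transcripts (median SD 0.127 against 0.769). Pairs of these 4 libraries had a chi-squared value per gene of 3.48 to 9.42, against 59.3 to 448.3 for pairs from 1 clone. Most pairs from 1 clone set a library with the transcripts against 1 without, as at 448.3, and pairs within a class gave 59.3, 89.8 and 144.7. These 4 libraries therefore held much in common beyond liver and heart transcripts, and little particular to their clones. The libraries bulk_6556c4_no1, bulk_6620c1_no1 and bulk_6694c2_no1 came next, at 10.06 to 44.1 with each other and with the 4. The clone sums include them, and what this did to differences between clones was not tested. What the common source was, and at which step it entered, stays open. The labels name no batch, but the tumour number in the titles tracks the transcripts. All 16 tumours numbered 1 had them, and of the other tumours with a phenotype only bulk_2669c4_no2 did. Whether that number stands for a batch was not tested.

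Cell cycle genes lower in T cell high clones (median log2 difference -0.26, camera adjusted p = 1.04e-05 with the preset correlation) stayed as low in the libraries without liver and heart transcripts, with a median of -0.24, 22 of 22 genes below 0 and a camera adjusted p = 8.31e-05, while the median of the fibroblast list went from 0.21 to 0.05. This argues against liver and heart RNA as the whole cause. Differences between single clones are not excluded as the cause, since the score did not go beyond their spread in all libraries (exact permutation p = 0.0979) or in those without the transcripts (0.209), and camera with an estimated correlation called neither (adjusted p = 0.718 and 0.806). A lower share of tumour cells in high tumours could lower these genes and stays open. The ductal epithelial list, taken here to mark tumour cells, had a median of 0.24 and a score difference of 0.41 in the other direction (camera adjusted p = 0.0189). It was not called in the libraries without the transcripts (median 0.09 with 11 genes up and 8 down, score difference 0.48, camera adjusted p = 0.0659). The high clone bulk_7160c2 lay apart on it at 8.11 against 6.78 to 7.22. Without that clone, members of the list still moved apart. Cldn7 (1.72), Epcam (1.61) and Esrp1 (1.60) lay higher, and Krt19 (-0.08), Krt8 (-0.27) and Spp1 (-0.85), also a macrophage list gene, did not. The list is therefore no direct measure of the share of tumour cells. A biological difference in division between phenotypes stays open and untested.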

How the results depend on the processing

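The tests with library class (libraries with or without liver and heart transcripts, or class as a term) were chosen after the result was seen, and the other settings were chosen in advance. All of them were run.

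Between high and low clones 0 genes were called, and this stayed 0 except for DESeq2 (25) and tumours as replicates (38), with 0 to 0 when each clone was left out. Between intermediate and low clones 0 became 939 with DESeq2, 421 with tumours as replicates, 130 with limma voom and 8 with voom and the class term. It became 567 without bulk_7160c2 and 9 without bulk_6499c3. Leaving out an intermediate clone leaves 1 in that group, so those counts are not given. Between high and intermediate clones 0 became 534 with DESeq2, 4 with tumours as replicates, 1 in the libraries without the transcripts and 1 without bulk_7160c2. The cause was not tested. On simulated high and low clones DESeq2 gave 19% false calls against 1.56% for edgeR.

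The 12 lists became 0 with an estimated correlation and 0 with fry, were 12 with RLE, 10 and 11 in the libraries without and with the transcripts, and 8 to 16 when a clone was left out. For the bulk_6499 clones, 5 genes became 0 without a filter, 0 with only their 4 tumours, 51 with DESeq2, 15 with the class term, and 0 to 13 when a tumour was left out. For the bulk_6556 clones, 0 became 2 with DESeq2. Leaving out a tumour leaves 1 in its clone. No conclusion is therefore drawn from that range for the bulk_6499 clones, and such counts are not given for the bulk_6556 clones. By Pearson's r, the 1 relation past the threshold became 0 in the libraries without the transcripts, where it still passed by rho (adjusted p = 0.00317 by the exact permutation test), and 3 in those with them. The cause was not tested.

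The replicate block by the number in the clone name gave 0 genes in each of the 3 comparisons of phenotypes, with 780, 861 and 765 at an unadjusted p under 0.05 and 3 residual degrees of freedom, and 14 lists (11 higher and 3 lower). Under it S100a8 (1.10), Cxcr2 (0.31), Csf2 (0.42), Gzmb (0.55), Prf1 (0.76), Krt19 (0.21) and Cd274 (-0.19) changed sign, none called. Deviations of the 4 pairs of clones across phenotypes correlated at -0.221, 0.212, 0.218 and 0.56, against a median of -0.007 and at most 0.354 in 73 other pairs. In the libraries without the transcripts, 2 of 3 pairs (0.319 and 0.509) lay above the highest other, 0.306. The pair that shares a number within a phenotype, low clones bulk_6419c1 and bulk_6419c5, correlated at 0.015 in all libraries and at 0.326 in those without. The bulk_6499 pair stayed below 0 in both, and the number was not taken to pair the clones. That pair alone cannot exclude a pairing, and in all libraries it includes bulk_6499c4_no1, which shows little of its clone. Deviations of the 2 intermediate clones, bulk_6422c5 and bulk_7160c5, are mirror images of each other, so the pairs that include them are not separate evidence. Whether some pairs are related stays open, and the main tests treated all clones as independent.

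Of 662 alternative values of the 24 preset genes, 622 kept their sign and 40, in 10 genes, changed sign without being called. None reversed a call. RLE moved the median of all genes by -0.01, -0.03 and 0.02 on the log2 scale. A low depth of 7.39 M counts limits the library bulk_6499c3_no1 for genes near 1 CPM.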

Other observations

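The count of adjusted calls over splits was a test chosen after the result was seen, as was the use of unadjusted counts once no gene had passed, while the splits for gene lists were planned.

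The unassigned library bulk_6883c4_no1 had a T cell score of 3.71 (mean log2 CPM of the list), where the 34 libraries with a phenotype reached at most 2.57. Its MHC class II score of 6.12 also lay above their highest, 5.92, and its interferon response score was 5.25 against at most 4.85. Other immune lists of this library also lay above the 34 and not all are printed, so these scores do not mark it as rich in T cells alone. The unassigned library bulk_6883c1_no1 had a T cell score of 2.65, an NK cell score of 1.49 against at most 0.61, and an interferon response score of 5.75. Its ductal epithelial score of 4.06 lay below the lowest of the 34, 5.58, and its granulocyte score of 0.51 below their lowest, 0.71. The unassigned library bulk_7062c3_no2 had a T cell score of -0.39, within the range of the 34, and its MAPK pathway feedback score of 6.97 lay just above their highest, 6.91. Liver and heart transcripts were found in bulk_6883c1_no1 and bulk_6883c4_no1, at 1.79% and 11.98% of the highest library, and not in bulk_7062c3_no2.

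Regrouping the 14 high and low clones tested whether the phenotype stands apart from other groupings, with 100 of 1716 possible splits drawn, the real one included. For genes at an unadjusted p under 0.05 the real split gave 1516 and the highest other 3636, and 19 splits gave as many, so chance cannot be excluded. For gene lists called by camera with the preset correlation the real split gave 12 and the highest other 23, and 42 splits gave as many, so chance cannot be excluded. For adjusted calls the real split gave 0, so all 100 splits had to give as many and the count says nothing about chance. The highest other was 81, and 3 splits called any gene. The split with 3636 genes may point to a structure of the clones other than the phenotype, but it is the highest of 100 and no such structure was tested. Over the splits, the count rose with the difference between the sides in the share of liver and heart transcripts (Spearman's rho = 0.488, over splits that are not independent). That difference was 5.36 percentage points for the real split, 11.4 in the median and 27.7 for the split with the highest count, but only 4.84 for the split with the second highest count (3552) and the 81 adjusted calls, so the share alone does not account for the counts.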
